A study of Homo sapiens with 36 samples.

How the data were processed

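RNA-seq was measured in 36 libraries of the established human lines HN4, HN6 and Cal27, 3 libraries in each of 12 groups: 6 groups of an IL-8 experiment and 6 of an ACLY plasmid experiment. Per the labels' protocols, cells were grown in serum depleted of exosomes, RNA was taken with TRIzol, and libraries were made from poly-A selected RNA primed with random hexamers. Per the submitters' processing notes, the tools were CASAVA, HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2, and the build was hg38. The strand setting, the annotation release and the treatment of reads that match several places were not given in the sources used here, so genes with near-identical copies (HSPA1A, MAGEA genes, SERF1B, SPRR2 genes, S100A7, KRT81, KRT6A) and overlapping or antisense genes are uncertain. The deposited values are whole-number counts per gene for 58735 genes, with no normalization. All 58735 gene identifiers had the start and end they have in GENCODE 29, whose names were used because 27 symbols had been turned into dates in the table. 1568 symbols stood on more than one gene, and 19951 genes were protein-coding.

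Groups and replicate numbers were taken from the labels. Library totals ran from 16570601 to 20232735 counts, and a count of 0 allows up to 0.148 to 0.181 CPM, the count scaled by library depth (3 counts of the total). This limit covers counting error only, since reads without molecular identifiers are not independent molecules. Counts of replicates of a group differed by more than sampling noise in every pair, so all 36 libraries were kept as separate replicates.

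The counts of each experiment were fitted with edgeR 4.0.16 (R 4.3.3, limma 3.58.1): TMM factors, filterByExpr by group with a minimum count of 10 and a minimum total of 15, a quasi-likelihood fit with robust dispersion, 1 mean per group, and 12 residual degrees of freedom over 18 libraries. This left 18399 genes in the IL-8 experiment and 18557 in the plasmid experiment, and ACLY, CXCR1, CXCR2 and CXCL8 were kept whatever their counts. Tests were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. A difference of the response among the 3 lines was tested with both interaction terms together, on 2 degrees of freedom. Levels were computed as CPM with TMM factors; the line-specific shares, the mixing estimate and the exact permutation tests used CPM of library totals. Levels of the 4 genes between untreated lines also had an exact two-sided permutation test, 12 tests in all, adjusted over the 12.

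The tests, the 21 gene lists, the rule for named genes and the alternatives were chosen before the data were examined, apart from those said to be added later. The lists covered NF-kB and TNF targets, CXCR1 and CXCR2 with their ligands, cholesterol synthesis, fatty acid synthesis, triglyceride and lipid droplets, fatty acid oxidation, the tricarboxylic acid cycle, glycolysis and hypoxia, interferon-stimulated genes, mesenchymal and invasion genes, squamous differentiation, stem cell associated genes, the cell cycle, p53 targets, the unfolded protein and integrated stress response, heat shock, immediate early genes, small extracellular vesicle formation, fibroblast markers, leukocyte and endothelial markers and mitochondrially encoded mRNAs. Each was tested with camera at a preset correlation of 0.01, adjusted over the 21 lists of a comparison (126 tests in 6 comparisons), and again with an estimated correlation. A list call holds with an estimated correlation unless its p under that setting is printed as lost. Named genes were ACLY, CXCR1, CXCR2 and CXCL8, the 8 largest rises and 8 largest falls among protein-coding genes past the threshold with mean log2 CPM of at least 1 and no overlap between the 3 and 3 libraries, and up to 4 called members of each list; some genes that meet this rule are not reported here. Genes shared by all 3 lines, and those named for their direction in more than one comparison, were chosen after their values were seen.

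Genes read in only 1 line were defined, after the data were seen, by at least 10 CPM in 1 untreated line and less than 0.5 in the others; Y-linked genes, XIST and TSIX were left out of them. A stricter form took 20 and 0.3 CPM. A mixture of HN4 and Cal27 controls at the share so estimated was compared with the observed changes over other genes.

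Alternatives were DESeq2 1.42.0 and its size factors, library-size and upper-quartile scaling, no filter and a filter at a mean of 5 CPM, the 6 libraries of a line alone, the replicate number as a block, each replicate left out, ACLY left out, a 2-fold limit, protein-coding genes alone, and fry for lists. Added after the data were seen were a fit without the library of lowest mitochondrial share in each experiment, all 36 libraries in 1 fit, in Cal27 genes within 1.2-fold of both HN4 groups, the HN4 plasmid direction turned, and the direction from Cal27 to HN4 or HN6 taken from the Cal27 controls of the other experiment, with TMM factors over 36 libraries. On simulated data with 200 changed genes, the fit of 18119 genes for HN4 with IL-8 recovered 53.7%, 77.6% and 98.5% of 1.5-fold, 2-fold and 4-fold changes with 8.33% false calls, and that of 18062 genes for Cal27 with ACLY recovered 74.6%, 89.6% and 100% with 5.38%. The real comparisons called 2567 to 11734 genes, so these rates need not hold for them. Simulated mixing of 0.3 and 0.6 was estimated as 0.284 and 0.581. The mixed libraries, replicate 1 of untreated HN4 and Cal27, were among those that defined the line-specific genes, which favours a close estimate. The list test called the changed list in both simulated comparisons that had one, and 1 unchanged list in HN6 with IL-8. Figures were drawn with matplotlib 3.10.9.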

Results

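Gene counts from RNA-seq were collected for 36 libraries of 3 established lines of human head and neck squamous cell carcinoma, HN4, HN6 and Cal27, in 12 groups of 3 libraries. In the first experiment each line was left untreated or given recombinant human interleukin-8 (IL-8), the neutrophil-attracting chemokine encoded by CXCL8, at 100 ng per ml for 24 h. The stated question was what IL-8 does in lines that differ in CXCR1, one of its receptors. In the second experiment each line was transfected with a plasmid carrying ACLY, the ATP-citrate lyase that makes cytosolic acetyl-CoA from citrate, or with the vector, to find what lies downstream of ACLY. The libraries held 16570601 to 20232735 counts. The labels number the replicates of each group but do not say whether they were separate cultures, so p-values measure the spread between these libraries, which may be technical. Levels are depth-scaled counts (CPM) with TMM factors, as mean ± SD with n = 3 in every group unless another unit is named, and folds come from the fitted model.

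CXCR1 was at the limit of detection in all 3 lines, while CXCR2, the other IL-8 receptor, was read mainly in Cal27. CXCR1 (chromosome 2, 218162845 to 218166995, hg38) had 1 read over the 3 untreated HN4 libraries, 0 over the HN6 libraries and 4 over the Cal27 libraries, and a count of 0 allows up to 0.148 to 0.181 CPM in a library. CXCR1 in Cal27 against HN6 had an edgeR log2 difference of 3.46 with adjusted p = 0.0506, and 3.52 with adjusted p = 0.0449 when edgeR was scaled by library size alone. CXCR2 (chromosome 2, 218125289 to 218137253) stood at 7.04 ± 0.861 CPM in untreated Cal27, 0.204 ± 0.18 in HN4 and 0.0374 ± 0.0324 in HN6. The edgeR log2 difference for CXCR2 was 5.08 from HN4 (adjusted p = 7.38e-10) and 7.30 from HN6 (adjusted p = 1.99e-10). For HN6 against HN4, which had 2 and 11 CXCR2 reads in all, it was -2.21 (edgeR adjusted p = 0.0382), and without untreated HN4 replicate 3 it was -1.34 (edgeR adjusted p = 0.278). The call was also lost without HN6 untreated replicate 1 (-2.54), 2 (-2.55) or 3 (-1.72). CXCL8 itself (chromosome 4, 73740506 to 73743716) was at 424 ± 13 CPM in untreated HN4, 184 ± 15.8 in HN6 and 443 ± 41.1 in Cal27. No difference of these genes between lines could pass an exact two-sided permutation test on CPM, whose smallest p for 3 against 3 libraries is 0.1.

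ACLY, the transfected gene (chromosome 17, 41866908 to 41930542, minus strand), rose in HN6 and Cal27 with its plasmid and was lower in the HN4 libraries labelled ACLY than in those labelled vector. It went from 269 ± 4.57 to 2218 ± 65.9 CPM in HN6 (8.26-fold, edgeR adjusted p = 8.99e-31) and from 232 ± 12.5 to 1900 ± 39.6 CPM in Cal27 (8.19-fold, edgeR adjusted p = 2.99e-31). HN4 libraries labelled vector held 1515 ± 10.5 CPM of ACLY and those labelled ACLY 351.5 ± 30.6 CPM, a log2 difference of -2.11 with a standard error of 0.0525 (edgeR adjusted p = 2.62e-26). The 3 libraries labelled ACLY had 5645 to 6447 ACLY reads and the 3 labelled vector had 25343 to 29445, so every library of the group goes against its label. With IL-8, ACLY rose in HN4 from 372.5 ± 5.83 to 1346 ± 17.6 CPM (3.61-fold, edgeR adjusted p = 4.65e-12) and in Cal27 from 235 ± 3.9 to 1169 ± 94 CPM (4.98-fold, edgeR adjusted p = 2.7e-14). In HN6 ACLY fell from 277 ± 3.59 to 223 ± 2.35 CPM (log2 change -0.31, edgeR adjusted p = 0.00232). The direction of every HN4 value in the plasmid experiment is given as the libraries were labelled.

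**Figure D1:**
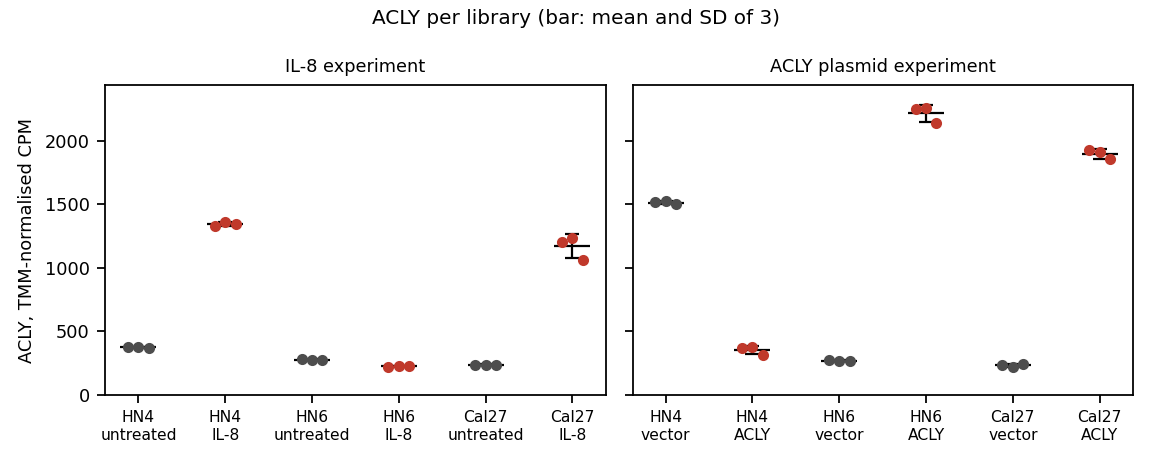
ACLY level (TMM-scaled CPM, vertical axis) in each library by line and group (horizontal axis), with the mean and SD of 3 libraries; grey points are controls and red points treated libraries. HN4 libraries labelled ACLY averaged 351.5 CPM against 1515 CPM in those labelled vector, while HN6 and Cal27 libraries labelled ACLY averaged 2218 and 1900 CPM.

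Genes otherwise read only in HN4 were read in the Cal27 libraries given IL-8 or the ACLY plasmid and were near 0 in the Cal27 controls. Over 37 genes read in untreated HN4 and hardly in the other lines, the median level was 0.264 ± 0.0417 of that in HN4 in Cal27 with IL-8 and 0.464 ± 0.0144 in Cal27 with the ACLY plasmid. It was 0.000326 ± 0.000565 in untreated Cal27 and 0 with the vector. PLIN2, which coats lipid droplets, stood at 92.6 CPM in untreated HN4, 0.348 in untreated Cal27 and 34.3 ± 5.77 in Cal27 with IL-8. Over 46 genes read only in Cal27, the median level was 0.622 ± 0.0474 and 0.391 ± 0.0201 of that in untreated Cal27. Over 24 genes read only in HN6, it was 7.6e-05 and 0.000554 of the HN6 level. Separately, Cal27 with IL-8 replicate 3 had 1.06% of its counts on mitochondrial genes, where the others of its group had 3.37% and 3.59%, and the third HN4 library labelled ACLY had 2.15% against 5.71% and 6.04%. These gene sets and both libraries were picked after the data were seen.

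**Figure D2:**
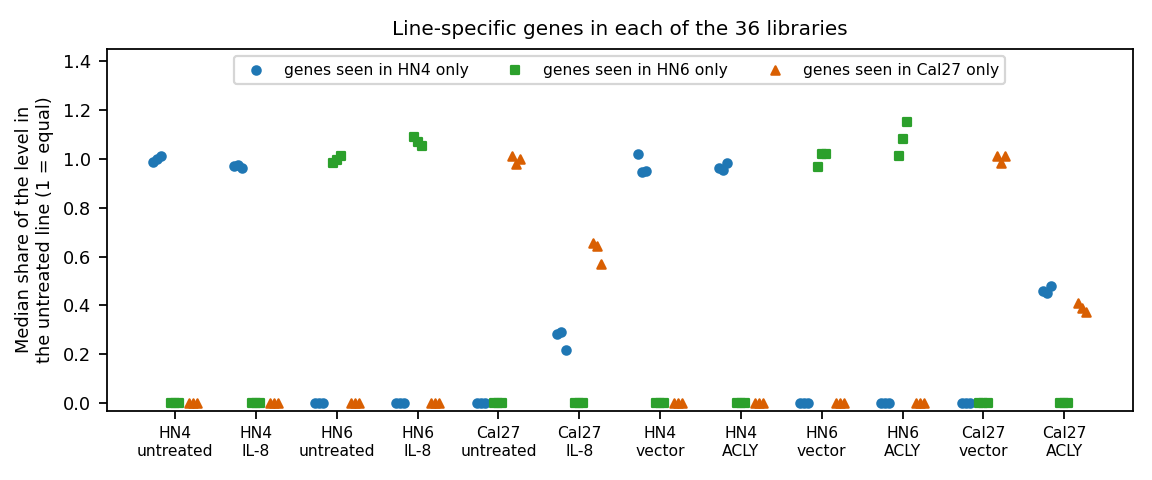
Median level of genes read only in HN4 (circles), only in HN6 (squares) or only in Cal27 (triangles), as a share of the level in the untreated line (vertical axis, 1 is equal), in each of the 36 libraries by group (horizontal axis). Cal27 libraries given IL-8 averaged 0.264 of the HN4 level and those given the ACLY plasmid 0.464, while Cal27 controls lie near 0.

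In HN4, genes of cell division, protein folding and cholesterol synthesis were higher with IL-8, and NF-kB targets, hypoxia genes and CXCL8 were lower. Whether these differences are particular to IL-8 cannot be told. HN4 labelled vector, whose ACLY level goes against its label, lay close to HN4 with IL-8. With all 36 libraries in 1 fit, HN4 with IL-8 and HN4 labelled vector differed in 17 of 19350 genes by edgeR. The same comparison gave 3615 genes in HN6 and 8332 in Cal27. Among the largest rises were MMP3, a matrix-degrading enzyme, from 1.25 ± 0.187 to 11.8 ± 0.411 CPM (9.41-fold), PKIB, an inhibitor of protein kinase A (5.06-fold), and VCAN, a matrix proteoglycan, from 29.4 ± 1.06 to 97.1 ± 5.79 CPM (3.30-fold). Among the largest falls were CHAC1, a stress-induced glutathione-degrading enzyme, from 19.0 ± 0.432 to 5.68 ± 0.443 CPM (log2 change -1.74), CA9, a hypoxia-induced carbonic anhydrase (-1.58), and TXNIP (-1.51). Of 30 cell cycle genes 21 rose and 0 fell, the same numbers when adjusted over the list alone (camera adjusted p = 1.02e-34). Among them were AURKA from 71.4 ± 4.97 to 173 ± 6.95 CPM (2.42-fold) and PLK1 from 26.9 ± 1.68 to 56.1 ± 1.74 CPM (2.08-fold), both mitotic kinases. Of 18 heat shock genes 14 rose and 0 fell, or 16 rose when adjusted over the list alone (camera adjusted p = 9.13e-21), with the chaperone HSPH1 at 290.5 ± 9.16 and 492 ± 14.8 CPM (1.70-fold). Of 23 cholesterol synthesis genes 8 rose and 0 fell, also when adjusted over the list alone (camera adjusted p = 2.11e-05), led by HMGCS1 (1.60-fold). Of 31 interferon-stimulated genes 10 rose and 1 fell, or 13 and 1 adjusted over the list alone (camera adjusted p = 6.82e-05). IFIT1 stood at 8.71 ± 0.586 and 17.7 ± 1.42 CPM.

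Of 24 NF-kB and TNF target genes 14 fell in HN4 with IL-8 and 0 rose, or 15 fell when adjusted over the list alone (camera adjusted p = 1.12e-11). TNFAIP3, which restrains NF-kB, went from 207 ± 6.83 to 118 ± 3.19 CPM (log2 change -0.81). Of 8 measured receptors and ligands of the IL-8 pathway 4 fell and 0 rose, also when adjusted over the list alone (camera adjusted p = 2.65e-05). CXCL8 went from 424 ± 13 to 194 ± 8.66 CPM (-1.13). In the glycolysis and hypoxia list 9 of 26 fell and 1 rose, or 9 and 2 adjusted over the list alone (camera adjusted p = 1.86e-07). NDRG1 went from 443 ± 3.19 to 161 ± 5.28 CPM (-1.46). In the unfolded protein and integrated stress response list 10 of 28 fell and 4 rose, or 12 and 5 adjusted over the list alone (camera adjusted p = 0.00891), and DDIT3 went from 21.2 ± 1.23 to 9.93 ± 1.3 CPM. That list lost its call with no filter on low counts (camera adjusted p = 0.0685). Of 20 p53 targets 5 fell and 0 rose, or 6 fell adjusted over the list alone (camera adjusted p = 0.00157). BBC3 stood at -1.05 and CDKN1A at -0.50. For 3 more lists the call was lost with an estimated correlation. In squamous differentiation 5 of 19 rose and 0 fell (camera adjusted p = 0.000131, and adjusted p = 0.0696 with an estimated correlation). In the tricarboxylic acid cycle 4 of 22 rose and 0 fell (camera adjusted p = 0.00532, and adjusted p = 0.0924 with an estimated correlation). In immediate early genes 4 of 25 fell and 1 rose (camera adjusted p = 0.0328, and adjusted p = 0.194 with an estimated correlation), and that call was also lost without HN4 IL-8 replicate 3 (0.0625) or untreated replicate 1 (0.0533). By edgeR, 2567 of 18399 genes passed an adjusted p of 0.05, 1267 higher and 1300 lower, and 416 of them changed at least 2-fold, 102 higher and 314 lower. The count was 6550 from the HN4 libraries alone, 5732 (3097 higher) without Cal27 IL-8 replicate 3, and 1403 and 1547 without HN4 IL-8 replicate 2 or 3 and 1604, 1606 and 1514 without untreated replicate 1, 2 or 3. Scaling by library size split it 792 higher to 1588 lower and upper-quartile scaling 813 to 1692.

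In HN6, IL-8 raised genes of the stress response and hypoxia and lowered genes of cell division, cholesterol synthesis and protein folding. CHAC1 rose from 1.2 ± 0.183 to 8.38 ± 0.392 CPM (6.97-fold), ALDH1L2, a mitochondrial folate enzyme, rose 6.30-fold, and NDRG1, a hypoxia-induced gene, went from 21.3 ± 2.14 to 102 ± 2.04 CPM (4.77-fold). ABCA1, a cholesterol exporter, rose 4.67-fold and VLDLR, a lipoprotein receptor, rose 4.78-fold. IFI27, an interferon-induced gene, fell from 4.39 ± 0.665 to 1.35 ± 0.146 CPM (log2 change -1.69), MMP7 from 42.8 ± 1.43 to 14.4 ± 0.687 CPM (-1.57), and FST, which binds activins, from 62.8 ± 2.95 to 21.5 ± 1.31 CPM (-1.54). Of 28 unfolded protein and integrated stress response genes 20 rose and 1 fell, or 23 and 1 adjusted over the list alone (camera adjusted p = 8.95e-38). They included ASNS, asparagine synthetase (7.0-fold), and DDIT4, from 51.2 ± 6.56 to 165 ± 9.55 CPM (3.22-fold). In the glycolysis and hypoxia list 11 of 26 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 2.34e-08). Of 8 measured fibroblast markers 4 rose and 0 fell, or 5 adjusted over the list alone (camera adjusted p = 0.00107). PDGFRB stood at 2.15 ± 0.559 and 4.89 ± 0.187 CPM. With the stricter filter the fibroblast list was not called (camera adjusted p = 0.283).

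Of 30 cell cycle genes 19 fell in HN6 with IL-8 and 0 rose, or 21 adjusted over the list alone (camera adjusted p = 6.5e-20). The proliferation marker MKI67 went from 1029 ± 76.1 to 580 ± 17.2 CPM (log2 change -0.83). Of 23 cholesterol synthesis genes 14 fell and 0 rose, or 16 adjusted over the list alone (camera adjusted p = 2.51e-15). Of 18 heat shock genes 10 fell and 0 rose, or 11 adjusted over the list alone (camera adjusted p = 1.3e-07). HSPA8 went from 2902 ± 94.4 to 1816 ± 80.7 CPM (-0.68). In the IL-8 receptor and ligand list 4 of 8 fell and 0 rose, or 4 and 1 adjusted over the list alone (camera adjusted p = 1.07e-06). Its median was -0.38 and its mean 0.05, which differ in sign. That mean includes CXCR1 (log2 change 1.86 on 0 and 1 read) and CXCR2 (2.45 on 2 and 13 reads), kept whatever their counts. CXCL8 fell from 184 ± 15.8 to 72.1 ± 1.46 CPM (-1.35) and CXCL1 from 188 ± 4.83 to 101 ± 2.84 CPM (-0.90). In NF-kB and TNF targets 5 of 24 fell and 2 rose (camera adjusted p = 0.0141, and adjusted p = 0.0519 with an estimated correlation). TNF fell from 23.1 ± 0.402 to 9.84 ± 0.812 CPM and IL1A rose 1.71-fold, and this list was not called with the stricter filter (camera adjusted p = 0.146). In fatty acid synthesis 6 of 23 fell and 0 rose (camera adjusted p = 0.00537, and adjusted p = 0.0519 with an estimated correlation). SCD, the stearoyl-CoA desaturase, went from 1058 ± 31.9 to 620 ± 8.34 CPM (-0.77). By edgeR, 2846 of 18399 genes passed, 1406 higher and 1440 lower, and 471 changed at least 2-fold, 79 of them lower. The count was 6019 from the HN6 libraries alone, 6193 (2868 higher) without Cal27 IL-8 replicate 3, 1742, 1786 and 1883 without HN6 IL-8 replicate 1, 2 or 3, and 1745 without untreated replicate 2. Scaling by library size split it 1691 higher to 937 lower and upper-quartile scaling 1761 to 999.

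In Cal27, the genes that moved most with IL-8 moved towards their level in HN4. KRT81, a hair keratin whose reads may be shared with related keratins, went from 1.63 ± 0.151 to 1628 ± 678 CPM and stood at 3766 CPM in untreated HN4. EEF1A2, a translation elongation factor, went from 3.19 ± 0.513 to 200 ± 103 CPM (509 in HN4), and COL8A1, a collagen chain with 2 reads over the untreated libraries, from 0.0355 to 30.6 ± 7.17 CPM (180 in HN4). MUC16, a membrane mucin, fell from 93.7 ± 8.39 to 28.2 ± 15.2 CPM (log2 change -1.73) and PDLIM3 from 4.14 ± 0.153 to 1.36 ± 0.506 CPM (-1.60), with 4.62 and 0 CPM in untreated HN4. SERF1B fell too, but shares reads with its copy SERF1A and is uncertain. Of 1820 genes called with at least a 2-fold change, 1266 higher and 554 lower, 97.4% moved towards the level of untreated HN4, as did 89.1% of all called genes, but the Cal27 controls enter both the change and the direction. With that direction taken from the vector libraries of Cal27, which share no library with the change, the shares were 96.4% and 88.6%, and towards HN6 they were 78.1% and 74.3%. The counts towards HN4 below use the vector libraries in this way, which was chosen after the data were seen.

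Heat shock genes and p53 targets rose in Cal27 with IL-8 on both forms of the list test. Of 18 heat shock genes 13 rose and 0 fell, or 15 adjusted over the list alone (camera adjusted p = 0.000333, and adjusted p = 0.0114 with an estimated correlation), and 3 of the 13 moved towards untreated HN4, 9 towards HN4 with IL-8 and 11 towards HN6. HSPH1 went from 208 ± 11.4 to 411 ± 35.2 CPM (1.98-fold) and HSPA8 from 1242 ± 58.9 to 2092 ± 120 CPM (1.69-fold), where untreated HN4 held 290.5 and 1429 CPM. Of 20 p53 targets 10 rose and 1 fell, or 10 and 2 adjusted over the list alone (camera adjusted p = 0.00445, and adjusted p = 0.0303 with an estimated correlation), and 11 of the 11 moved towards HN4. MDM2, a p53-induced ligase of p53, rose from 41.7 ± 4.94 to 139 ± 15.3 CPM (3.32-fold; 325 in HN4) and CDKN1A, a cell cycle inhibitor, from 68.8 ± 2.5 to 169 ± 9.01 CPM (2.45-fold; 408 in HN4). Of the 11 p53 targets 7 moved towards HN6.

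The camera calls of 7 further lists in Cal27 with IL-8 were lost with an estimated correlation. In glycolysis and hypoxia 13 of 26 fell and 2 rose, 13 of the 15 towards HN4 and 14 towards HN6 (camera adjusted p = 0.00417, and adjusted p = 0.133 with an estimated correlation). NDRG1 went from 749.7 ± 29.4 to 404 ± 25.3 CPM. In mesenchymal and invasion genes 12 of 28 fell and 5 rose, 15 of the 17 towards HN4 and 13 towards HN6 (camera adjusted p = 0.0159, and adjusted p = 0.305 with an estimated correlation). MMP13 fell by 1.33 on the log2 scale. In the cell cycle list 13 of 30 rose and 2 fell, 12 of the 15 towards HN4 and 13 towards HN6 (camera adjusted p = 0.0372, and adjusted p = 0.188 with an estimated correlation), and PCNA rose 1.67-fold. That call was lost without IL-8 replicate 1 (0.0762) or 2 (0.0572) or untreated replicate 1 (0.0612). Fatty acid oxidation had 9 of 22 higher and 2 lower, 10 of the 11 towards HN4 and 9 towards HN6 (camera adjusted p = 0.0187, and adjusted p = 0.114 with an estimated correlation). ACAA2 went from 1.18 ± 0.139 to 14 ± 1.21 CPM (41.4 in HN4). Triglyceride and lipid droplet genes had 6 of 21 higher and 4 lower, 9 of the 10 towards HN4 and 8 towards HN6 (camera adjusted p = 0.0473, and adjusted p = 0.114 with an estimated correlation). PLIN2 was among them, and the call was lost without IL-8 replicate 1 (0.072) or untreated replicate 2 (0.0527) or 3 (0.0574). Leukocyte and endothelial markers had 4 of 6 lower, 4 of the 4 towards HN4 and 4 towards HN6 (camera adjusted p = 0.0372, and adjusted p = 0.114 with an estimated correlation), VWF going from 4.09 ± 0.533 to 1.87 ± 0.539 CPM. That call was lost without IL-8 replicate 1 (0.0773), 2 (0.0531) or 3 (0.0733) or untreated replicate 3 (0.0574). Mitochondrially encoded mRNAs had 5 of 13 lower (camera adjusted p = 0.00711, and adjusted p = 0.555 with an estimated correlation), in the group whose replicate 3 had 1.06% mitochondrial counts. CXCR2 fell from 7.04 ± 0.861 to 3.62 ± 0.374 CPM (log2 change -0.96, edgeR adjusted p = 0.00375). CXCL8 had a log2 change of -0.19 (edgeR adjusted p = 0.049), lost in 7 of 17 alternatives, among them without IL-8 replicate 1 (0.0746) or 2 (0.081) and without untreated replicate 2 (0.145) or 3 (0.229). By edgeR 7247 of 18399 genes passed, 4176 higher and 3071 lower, against 2587 from the Cal27 libraries alone and 3473 higher to 3951 lower with upper-quartile scaling. Among 2740 genes whose untreated Cal27 level lay within 1.2-fold of both HN4 groups, a set chosen after the data were seen, 425 passed and 7 of them changed at least 2-fold.

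The HN4 libraries labelled ACLY held more of the NF-kB, stress response and hypoxia transcripts and less of the cell division and heat shock transcripts than those labelled vector. CHAC1 stood at 34.6 ± 2.12 against 3.83 ± 0.892 CPM (8.95-fold), CA9 at 45.2 ± 8.88 against 6.14 ± 0.518 CPM (7.38-fold). TXNIP, which limits glucose uptake, stood at 91.3 ± 2.18 against 14.4 ± 1.25 CPM (6.36-fold). MMP3 was lower, at 1.42 ± 0.479 against 17.1 ± 1.83 CPM (log2 difference -3.57), as were PKIB (-2.47), VCAN (-1.99) and SPP1, the matrix protein osteopontin (-1.85). Of 24 NF-kB and TNF targets 22 were higher and 0 lower, or 23 adjusted over the list alone (camera adjusted p = 5.49e-23). Of 8 receptors and ligands 4 were higher and 0 lower, also adjusted over the list alone (camera adjusted p = 3.6e-09). CXCL8 stood at 494 ± 34.1 against 146 ± 10.8 CPM (3.38-fold). In the unfolded protein and integrated stress response list 16 of 28 were higher and 5 lower, or 17 and 6 adjusted over the list alone (camera adjusted p = 7.06e-19), DDIT3 at 5.06-fold. In glycolysis and hypoxia 11 of 26 were higher and 6 lower, or 12 and 6 adjusted over the list alone (camera adjusted p = 1.07e-07), NDRG1 at 3.92-fold. In immediate early genes 15 of 25 were higher and 3 lower, or 16 and 3 adjusted over the list alone (camera adjusted p = 5.2e-08), HBEGF at 3.14-fold. In p53 targets 11 of 20 were higher and 2 lower, also adjusted over the list alone (camera adjusted p = 5.94e-08), BBC3 at 3.44-fold. In mesenchymal and invasion genes 14 of 28 were higher and 4 lower, also adjusted over the list alone (camera adjusted p = 5.85e-05). The third library labelled ACLY, with 2.15% mitochondrial counts, belongs to this group.

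Of 30 cell cycle genes 27 were lower and 0 higher in HN4 labelled ACLY, or 29 adjusted over the list alone (camera adjusted p = 1.88e-40). AURKA stood at 72.1 ± 3.03 against 191 ± 2.51 CPM (log2 difference -1.41). Of 18 heat shock genes 17 were lower and 0 higher, also adjusted over the list alone (camera adjusted p = 2.52e-33). HSPH1 stood at 238 ± 12 against 540 ± 6.63 CPM (-1.18). In cholesterol synthesis 13 of 23 were lower and 2 higher, also adjusted over the list alone (camera adjusted p = 0.000678), HMGCS1 at 222 ± 0.196 against 345 ± 5.03 CPM. In squamous differentiation 7 of 19 were lower and 0 higher, also adjusted over the list alone (camera adjusted p = 0.00302), the keratin KRT6A at 4.83 ± 0.87 against 15.3 ± 1.76 CPM. Interferon-stimulated genes had 14 of 31 lower and 3 higher (camera adjusted p = 0.0417, and adjusted p = 0.102 with an estimated correlation). The tricarboxylic acid cycle had 8 of 22 lower and 2 higher (camera adjusted p = 0.0461, and adjusted p = 0.102 with an estimated correlation). Without labelled-ACLY replicate 1 or vector replicate 2 that list was not called (0.0665 and 0.0623). By edgeR 7068 of 18557 genes passed, 3516 higher and 3552 lower, and 1273 differed at least 2-fold, 968 of them higher. Upper-quartile scaling split the count 4403 higher to 2741 lower.

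In HN6, the ACLY plasmid raised genes of hypoxia, interferon response, NF-kB signalling and cholesterol synthesis and lowered genes of cell division and protein folding. NDRG1 rose from 23.9 ± 0.587 to 415 ± 17.5 CPM (17.4-fold) and CXCL11, an interferon-induced chemokine, from 0.723 ± 0.233 to 12 ± 2.08 CPM (16.4-fold). CASP14, a caspase of keratinocyte differentiation, rose from 2.9 ± 1.25 to 40.9 ± 0.0761 CPM (14.1-fold), and VNN1 10.5-fold. CDCA7, a MYC-responsive gene, fell from 107 ± 5.01 to 29 ± 0.41 CPM (log2 change -1.88). LYAR, a nucleolar protein, went from 64.4 ± 5.35 to 19.0 ± 0.658 CPM (-1.76), and TERT, the telomerase catalytic subunit, from 6.58 ± 0.795 to 1.65 ± 0.341 CPM (-1.99). Of 30 cell cycle genes 30 fell, also adjusted over the list alone (camera adjusted p = 2.92e-36). AURKA went from 312 ± 9.13 to 137 ± 1.93 CPM (-1.19). Of 18 heat shock genes 15 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 1.66e-15). HSPA8 went from 2869 ± 220 to 1186 ± 32.7 CPM (-1.27). In glycolysis and hypoxia 19 of 26 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 2.41e-16). BNIP3 went from 50.4 ± 2.64 to 187 ± 0.489 CPM (3.71-fold). In NF-kB and TNF targets 19 of 24 rose and 1 fell, or 21 and 1 adjusted over the list alone (camera adjusted p = 1.23e-09). IL1A went from 43.3 ± 2.8 to 144.5 ± 2.86 CPM (3.34-fold). Leukocyte and endothelial markers, not called as a list (camera adjusted p = 0.056), had 6 of 7 higher and 0 lower, also adjusted over the list alone, with a median log2 change of 1.17. Fibroblast markers, not called either (camera adjusted p = 0.112), had 4 of 7 higher and 0 lower, or 5 and 1 adjusted over the list alone, with a median of 1.02.

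Of 8 receptors and ligands 6 rose and 0 fell in HN6 with the ACLY plasmid, or 7 adjusted over the list alone (camera adjusted p = 4.29e-06). Some members were near the floor. CXCL5, called as higher, stood at 0 and 0.139 CPM of library totals and lost its call in 2 of 16 alternatives. CXCR1 had 0 reads in both groups. CXCR2 had 1 and 8 reads, with a log2 change of 2.56 (edgeR adjusted p = 0.0704). CXCL8 went from 192 ± 10.8 to 466 ± 4.47 CPM (2.42-fold) and CXCL6 from 9.41 ± 0.716 to 40.6 ± 4.93 CPM (4.31-fold). Of 23 cholesterol synthesis genes 16 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 3.8e-05). INSIG1, a sterol sensor, went from 87.4 ± 2.2 to 201 ± 2.14 CPM (2.30-fold). Of 31 interferon-stimulated genes 21 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.000207). STAT2 went from 56.3 ± 3.11 to 142 ± 3.33 CPM (2.52-fold). Mesenchymal and invasion genes had 16 of 28 higher and 8 lower, also adjusted over the list alone (camera adjusted p = 1.42e-05). ZEB2 was 3.01-fold higher and PDPN lower, at a log2 change of -1.80. In squamous differentiation 11 of 19 rose and 2 fell, or 13 and 2 adjusted over the list alone (camera adjusted p = 0.00114). S100A9 went from 46.7 ± 4.07 to 172 ± 4.91 CPM (3.67-fold). The unfolded protein and integrated stress response list had 19 of 28 higher and 5 lower (camera adjusted p = 0.000305, and adjusted p = 0.0717 with an estimated correlation). DDIT4 was 4.29-fold higher. By edgeR 9583 of 18557 genes passed, 4970 higher and 4613 lower, and 2338 changed at least 2-fold, 1815 of them higher.

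In Cal27 with the ACLY plasmid, as with IL-8, the genes that moved most moved towards their level in HN4. KRT81 went from 1.52 ± 0.388 to 2306 ± 165 CPM (3422 in HN4 labelled vector). SLC20A2, a phosphate transporter with 1 read over the vector libraries, went to 51.1 ± 3.01 CPM (111 in HN4). MAGEA12, one of a family of similar genes that may share reads, had 0 reads with vector and 39.1 ± 1.81 CPM with ACLY. MUC16 fell from 111 ± 1.23 to 9.19 ± 0.232 CPM (log2 change -3.60), PIGR, the receptor that carries antibodies across epithelia, from 12 ± 0.662 to 1.11 ± 0.405 CPM (-3.44), and MAP2 from 13.6 ± 0.499 to 1.06 ± 0.404 CPM (-3.68). Of 4264 genes called with at least a 2-fold change, 1930 higher and 2334 lower, 99% moved towards HN4 labelled vector, as did 93.5% of all called genes. With the direction taken from untreated Cal27 libraries in place of the vector ones the shares were 98.2% and 92.6%, towards HN4 labelled ACLY 96% and 85.5%, and towards HN6 80.3% and 72.9%. The counts below use the untreated Cal27 libraries in this way, and "HN4" is the group labelled vector unless labelled ACLY is said. Mitochondrial genes held 3.16% to 3.27% of the counts with ACLY and 4.53% to 5.01% with vector. Leukocyte and endothelial markers, not called as a list (camera adjusted p = 0.0508), had 5 of 7 lower and 0 higher, also adjusted over the list alone, with a median log2 change of -1.01. Fibroblast markers, not called either (camera adjusted p = 0.45), had 4 of 7 lower and 2 higher, also adjusted over the list alone, with a median of -1.51.

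Of 26 glycolysis and hypoxia genes 21 fell in Cal27 with the ACLY plasmid and 3 rose, also adjusted over the list alone (camera adjusted p = 2.3e-08), 22 of the 24 towards HN4 (21 towards HN4 labelled ACLY and 21 towards HN6). NDRG1 went from 789 ± 37.2 to 166 ± 3.86 CPM (log2 change -2.25; 95.9 in HN4). Of 18 heat shock genes 16 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 2.02e-07), 13 of the 16 towards HN4 but 4 towards HN4 labelled ACLY, and 14 towards HN6. HSPA8 went from 1085 ± 18.3 to 2553 ± 63.3 CPM (2.35-fold; 2456 in HN4). Of 20 p53 targets 12 rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.000157), 15 of the 16 towards HN4 (15 towards labelled ACLY and 12 towards HN6). CDKN1A went from 69.7 ± 4.77 to 276 ± 10.2 CPM (3.97-fold; 257 in HN4). In the cell cycle list 19 of 30 rose and 4 fell, or 20 and 5 adjusted over the list alone (camera adjusted p = 0.000409), 18 of the 23 towards HN4 (15 towards labelled ACLY and 18 towards HN6). PCNA went from 187 ± 6.96 to 410 ± 1.44 CPM (2.19-fold). In immediate early genes 13 of 25 rose and 6 fell, or 13 and 7 adjusted over the list alone (camera adjusted p = 0.00771), 15 of the 19 towards HN4 (14 towards labelled ACLY and 14 towards HN6). EREG, an EGFR ligand, went from 50.9 ± 3.81 to 278 ± 11.7 CPM (5.46-fold; 829 in HN4). With the replicate number as a block this list was not called (camera adjusted p = 0.053). Mesenchymal and invasion genes had 15 of 28 lower and 7 higher, 21 of the 22 towards HN4, 19 towards labelled ACLY and 15 towards HN6 (camera adjusted p = 0.00517, and adjusted p = 0.0822 with an estimated correlation). MMP13 fell from 16.8 ± 1.26 to 1.69 ± 0.155 CPM. The unfolded protein and integrated stress response list had 15 of 28 lower and 7 higher, 18 of the 22 towards HN4, 12 towards labelled ACLY and 17 towards HN6 (camera adjusted p = 0.0423, and adjusted p = 0.283 with an estimated correlation). It was not called without ACLY replicate 2 (0.0517), or without the third HN4 library labelled ACLY (0.0625), which enters the same fit.

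CXCR2 fell in Cal27 with the ACLY plasmid from 6.78 ± 1.15 to 0.792 ± 0.252 CPM (log2 change -3.10, edgeR adjusted p = 2.95e-10), with 0.142 CPM in HN4 labelled vector. CXCR1 had 13 reads over the vector libraries, 10 of them in replicate 1, and 0 with ACLY, and its edgeR adjusted p of 0.00998 became 0.123 without that replicate and 0.452 with DESeq2. CXCL8 went from 380.5 ± 14.7 to 327 ± 11.7 CPM (log2 change -0.22, edgeR adjusted p = 0.000797). By edgeR 11734 of 18557 genes passed, 6352 higher and 5382 lower. Upper-quartile scaling split them 4995 higher to 6864 lower, and it shifted all genes of the comparison by -0.15 on the log2 scale. Among 2338 genes whose vector level in Cal27 lay within 1.2-fold of both HN4 groups, 1024 passed and 12 of them changed at least 2-fold.

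**Figure D3:**
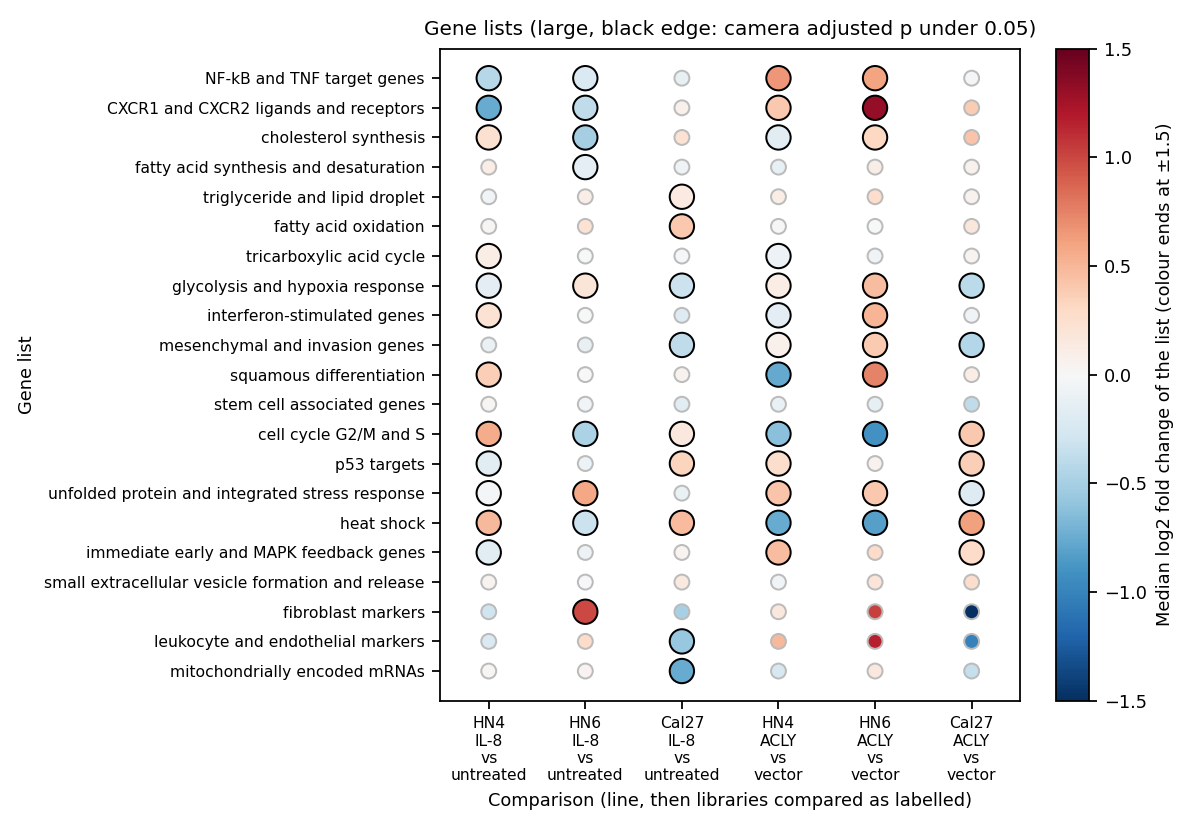
Median log2 fold change (colour, red higher and blue lower) of the 21 gene lists (vertical axis) in the 6 comparisons (horizontal axis), where a large point with a black edge has a camera adjusted p under 0.05. The cell cycle list rose in HN4 with IL-8 (21 of 30 genes) and fell in HN6 with IL-8 (19 of 30).

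Stem cell associated genes and genes of small extracellular vesicle formation were called as lists in none of the 6 comparisons, with camera adjusted p from 0.354 to 0.91 and from 0.056 to 0.879. Single members moved: ALDH1A3, an aldehyde dehydrogenase, rose 12-fold in Cal27 with IL-8 to 242 ± 18.5 CPM (791 in HN4), and in HN6 with the ACLY plasmid the vesicle genes SDCBP (1.68-fold) and CD9 (1.61-fold) were among 16 of 30 that rose, while 4 fell.

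The response to IL-8 differed among the 3 lines for 7398 of 18399 genes, and the response to the plasmid, with HN4 as labelled, for 13169 of 18557, by edgeR's test of both interaction terms together (adjusted p under 0.05). With the HN4 direction turned the plasmid count was 13575. The Cal27 part of these tests holds genes read only in HN4, raised in its treated libraries to 0.264 and 0.464 of the HN4 level. HN6 against HN4, a contrast without Cal27, differed in 4000 genes with IL-8 and, as labelled, 5788 with the plasmid. CHAC1, NDRG1 and CA9 fell in HN4 and Cal27 and rose in HN6 with IL-8, with edgeR adjusted p for the difference of 8.68e-10, 1.82e-13 and 4.22e-08. ACLY itself differed in its IL-8 response (edgeR adjusted p = 1.12e-12), as did CXCL8 (edgeR adjusted p = 4.86e-07), although the CXCL8 change of HN4 and HN6 differed by a log2 of only -0.22 (edgeR adjusted p = 0.151). Of 9574 genes called in any line with IL-8, 1470 were higher in one line and lower in another, and with the plasmid, taking HN4 as labelled, 6169 of 15262 were. With the HN4 direction turned, a setting chosen after the data were seen, that number was 6969.

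The responses of HN4 and HN6 to IL-8 went against each other more often than together. Of genes called in both, 111 moved the same way, where independent lists would share 198.6, and 757 moved opposite ways, where 198.5 were to be expected of independent lists (Pearson r across 13329 genes -0.275; genes are not independent replicates). HN4 and Cal27 shared 1033 genes of the same direction with IL-8 (504.6 for independent lists) and had 297 opposite (506.5), and HN6 and Cal27 shared 526 (559.5) and had 857 opposite (561.5). In treated Cal27, genes read only in HN4 were raised to 0.264 of the HN4 level with IL-8 and 0.464 with the plasmid. What Cal27 shares with the other lines, or does not, cannot be told apart from that rise. Genes moving the same way in all 3 lines with IL-8 numbered 54, where independent lists would share 38.96, and among them SPP1, NNMT and MANF rose and C5AR1, C5 and CPE fell. That number was 202 without Cal27 IL-8 replicate 3, 23 with the replicate number as a block, and 30 to 35 without any one of HN4 IL-8 replicates 2 and 3, HN4 untreated replicates 1 to 3 and HN6 IL-8 replicates 1 to 3. With the plasmid, taking HN4 as labelled, 712 genes moved the same way in all 3 lines, where independent lists would share 578.4, and among them CASP14, IL17C and GDF15 were higher and PAG1, MMP1 and KCTD12 lower. With the HN4 direction turned 287 genes moved the same way in all 3 lines, where independent lists would share 579.1, and none of these 6 did. HN4 labelled ACLY and HN6 shared 4099 genes of the same direction (1825 for independent lists; r = 0.418). HN4 labelled ACLY and Cal27 had 3657 in opposite directions (2236 for independent lists; r = -0.148), and HN6 and Cal27 had 4770 in opposite directions (3020 for independent lists; r = -0.135).

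Within a line, the IL-8 and plasmid responses ran together in Cal27 and, with HN4 as labelled, opposite in HN4. In HN4 as labelled, 2139 genes called in both moved opposite ways and 0 the same way (r = -0.701 across 13242 genes), for example TXNIP, lower with IL-8 (log2 -1.51) and higher in the libraries labelled ACLY (6.36-fold). With the HN4 direction turned these 2139 genes would move the same way, and the sign of r would turn. In Cal27 6719 moved the same way and 0 opposite ways (r = 0.95), for example MDM2 at 3.32-fold and 4.39-fold, where 2339 were to be expected of independent lists. In the treated groups of Cal27, genes read only in HN4 stood at 0.264 and 0.464 of the HN4 level, and whatever raised them enters both responses. A mixture with HN4 predicted the 2 changes with r = 0.847 and 0.888, and with HN6 in place of HN4 with 0.551 and 0.521. The Cal27 controls enter both the observed and the predicted change, which can raise r. Whether the 2 responses share more than the rise of HN4 genes cannot be told from these values. In HN6 2025 moved the same way and 184 opposite ways (r = 0.46), with NDRG1 at 2.25 and 4.12 but CXCL8 lower with IL-8 (log2 -1.35) and higher with the plasmid (2.42-fold). By their labels, no control library was shared between the experiments or lines. Vector and untreated libraries of HN6 and of Cal27 differed in 0 genes by edgeR, and the labels do not say whether cultures were shared.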

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

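The correlations with a mixture and the counts over other splits of the libraries were planned before their results were seen; the other tests here were chosen only after the result was seen. The response to IL-8 differed among the lines for 7398 genes and the response to the plasmid, with HN4 as labelled, for 13169 (13575 with the HN4 direction turned), by edgeR's joint test of the interaction terms. In 40 drawn splits within lines 1 of 40, the real one, reached either count, and the highest of the others called 4632 and 9394 genes. The splits mix treated and control libraries of a line, so they bear on any response and cannot show that responses differ among lines. Exchanging the HN4 vector and ACLY groups, a split that was not drawn, called 13575 genes, above the real 13169. Both counts include Cal27 and its raised HN4 genes, described below. For the 6 counts of single comparisons the 10 splits are too few for a share under 0.05; 1 of 10, the real one, gave the counts of 2567, 2846, 7247, 7068, 9583 and 11734, and the highest other split called 1, 1, 0, 0, 0 and 0 genes.

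Single genes whose response differed among the lines with IL-8 were ACLY (edgeR adjusted p = 1.12e-12), CXCR2 (edgeR adjusted p = 0.0152) and CXCL8 (edgeR adjusted p = 4.86e-07), with 174 of 200 further named genes, which were picked for their changes in single lines (40.2% of all genes). CXCR2 rests on 2 and 13 reads in HN6 without and with IL-8, a change not called itself (edgeR adjusted p = 0.0666), and Cal27 against HN4 had an edgeR adjusted p of 0.792. With the plasmid, taking HN4 as labelled, they were ACLY (edgeR adjusted p = 9.86e-35), CXCR2 (edgeR adjusted p = 2.16e-05) and CXCL8 (edgeR adjusted p = 3.77e-21), with 191 of 206 further named genes (71% of all genes; 198 with the HN4 direction turned, where ACLY, CXCR2 and CXCL8 passed too).

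In the Cal27 libraries given IL-8 or the ACLY plasmid, genes read only in HN4 stood at 0.264 and 0.464 of their HN4 level (0.293 and 0.545 with the stricter definition) and those read only in Cal27 at 0.622 and 0.391 of theirs. The tables argue against a general switching on of silent genes, since the median over genes read only in HN6 reached at most 0.0012 of their level in any of these libraries, and against whole libraries of the wrong line, since the median over genes read only in Cal27 stayed at 0.372 or more. HN4 cells or RNA mixed into these libraries may be the source: over genes not used to estimate the share, a mixture predicted the changes with r = 0.847 for IL-8 (0.551 with HN6 in place of HN4) and 0.888 for ACLY (0.521), and after allowing for it 4.61% of 738 and 17.5% of 1967 genes that changed at least 2-fold were left. The Cal27 controls enter both the observed and the predicted change, so part of each r can come from them. The highest ACLY level of the HN4 groups was 1323 CPM in the IL-8 experiment and 1486 CPM in the plasmid experiment. Mixing at that level gives 529 and 820 CPM in Cal27. ACLY stood at 1174 and 1879 CPM, 4.11 and 42.2 SD higher. That SD is the spread of the treated libraries and leaves out the error of the share. With IL-8 this argues against mixing with these HN4 groups alone as the source of the ACLY rise. The plasmid libraries were given ACLY itself, so their ACLY level cannot decide on mixing. HN4 material with more ACLY than these groups was not tested and stays open. The mitochondrial share averaged 2.67% with IL-8, where mixing with the lowest HN4 library gives no less than 4.77%. This argues against mixing alone there. With the plasmid it averaged 3.21% against 3.43% at a share of 0.464. That limit depends on the share, which was 0.545 by the stricter definition, so it cannot decide. Genes read only in Cal27 kept 0.622 and 0.391 of their level, where simulated shares of 0.3 and 0.6, both above the estimates, left 0.715 and 0.399. This argues against dilution at the estimated shares as the only source of these levels. With the plasmid PPP2R2B went from 27.5 to 2.23 CPM of library totals, but HS6ST2 only from 54.9 to 39.5. A shift of Cal27 cells themselves towards an HN4-like state remains open and was not tested apart from mixing, and where any HN4 RNA entered was not tested.

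ACLY was lower in HN4 libraries labelled ACLY than in those labelled vector. The tables argue against plasmid transcripts escaping the count, since ACLY rose by at least 3.033 on the log2 scale in HN6 and Cal27, and against the vector raising ACLY in every line, since vector against untreated gave log2 values no higher than -0.01768 there. An exchange of the labels may be the source: 173 genes separated untreated HN4 from the libraries labelled ACLY against 5041 for those labelled vector, and in HN6 and Cal27 vector and untreated libraries differed in 0 genes by edgeR (670 and 502 at an unadjusted p under 0.05; no other tool was run). Correlations of the labelled HN4 response with the other lines were r = 0.418 with HN6, which an exchange would turn negative, and r = -0.148 with Cal27 (3657 genes opposite, where independent lists would share 2236), which it would turn positive. Of the Cal27 calls 92.6% moved towards HN4 labelled vector, so the r with Cal27 cannot be read as a response to ACLY and cannot decide on the labels. Untreated and transfected libraries come from different experiments, HN4 labelled vector differed from HN4 with IL-8 in 17 genes, and a response of HN4 opposite to the other lines was not tested.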

How the results depend on the processing

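The fit without the library of lowest mitochondrial share, the single fit of 36 libraries, the set near HN4 levels and the turned HN4 direction were chosen only after the data were seen. Over the alternatives run for single genes and lists, which leave out the turned HN4 direction, 0 of 9215 named-gene values and 0 of 2394 list values changed sign while called in either fit; 8881 and 2165 kept their side of the threshold, 330 and 63 lost the call, and 4 and 166 gained it. Part of this was fixed beforehand. The 126 list values of fry's mixed test took their direction from camera. The 126 with an estimated correlation used the same gene statistics, so neither set could change sign. Most named genes were picked for being called, which makes a change of sign unlikely. With a 2-fold limit the counts were 416, 471 and 1820 with IL-8 in HN4, HN6 and Cal27, and 1273, 2338 and 4264 with the plasmid. With the 6 libraries of a line alone they were 6550, 6019 and 2587 with IL-8, and 84 genes moved the same way in all 3 lines. Without Cal27 IL-8 replicate 3 they were 5732 in HN4 and 6193 in HN6, with 202 genes shared by all 3 lines; that library enters the spread estimate of every IL-8 comparison. In the set near HN4 levels, which has fewer genes, Cal27 counts were 425 with IL-8 and 1024 with the plasmid. All 36 libraries in 1 fit moved none of the 6 comparison counts by over 1.5 times. With the HN4 plasmid direction turned, 287 genes moved the same way in all 3 lines and 13575 differed among lines.

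With the replicate number as a block the HN4 IL-8 count was 1614, the shared IL-8 genes 23 and CXCR2 in HN6 against HN4 -3.05 (edgeR adjusted p = 0.056), while CXCR1 in HN6 against HN4 went from -1.86 to 0.50, called in neither fit. No steady pairing by number was seen: same-number deviations correlated from -0.447 to 0.422. Only with the plasmid in HN6 was every library closest to its own number (0.0625 to 0.102). The labels do not say what the numbers mark, so shared days or cultures are not excluded. CXCR2 in HN6 against HN4 was -2.38 with DESeq2 (adjusted p = 0.0506) and -2.63 to -1.34 with 1 library left out. Its call was lost without HN4 untreated replicate 3 and without each HN6 untreated replicate. CXCR1 in Cal27 against HN6 passed with library size (3.52), the stricter filter (3.50) and upper quartile (3.54). Lists called with fry's directional test were 19 in Cal27 with IL-8 and 19 in HN6 and 20 in Cal27 with the plasmid. With fry's mixed test, which has no direction, they were 20 in HN6 and 21 in Cal27 with IL-8 and 20, 20 and 21 in HN4, HN6 and Cal27 with the plasmid. With an estimated correlation 2 lists remained in Cal27 with IL-8. The cause was not tested for these.

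Leaving out each library of the 2 groups compared in turn gave counts of 1403 to 1786, 1742 to 2040 and 5482 to 7876 with IL-8 and 6082 to 7193, 8733 to 8934 and 10894 to 11186 with the plasmid in HN4, HN6 and Cal27. Leaving out a library of another line can go beyond these ranges: without Cal27 IL-8 replicate 3 the counts were 5732 in HN4 and 6193 in HN6, and without the third HN4 library labelled ACLY they were 10266 in HN6 and 12400 in Cal27. Other libraries were not left out across lines for these counts. Differences among lines ran from 6361 to 10298 and 12712 to 13679 genes, and shared genes from 30 to 202 with IL-8 and 598 to 740 with the plasmid. With the same libraries of the line left out, lists called ran from 11 to 12, 9 to 9 and 6 to 10 with IL-8 and 13 to 15, 10 to 13 and 6 to 11 with the plasmid (11 without Cal27 ACLY replicate 1 or 3), and without Cal27 IL-8 replicate 3 they were 14 in HN4 and 10 in HN6. CXCR1 ran from 1.11 to 3.46 in Cal27 against HN4, 3.07 to 3.64 against HN6 and -2.35 to 0 in HN6 against HN4, and CXCR2 from 4.66 to 5.95 and 6.80 to 7.63 in Cal27 against HN4 and HN6. CXCR1 had 0 to 10 reads per library.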

Other observations

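The tests on the 2 libraries below were chosen only after the result was seen. Members of lists not called moved in single lines. In HN6 with the ACLY plasmid, the p53 target TP53INP1 rose 9.09-fold and EGR1, an immediate early transcription factor, 9.73-fold. In Cal27 with IL-8, CSF3, the granulocyte colony-stimulating factor, went from 1.48 to 29.2 CPM, and untreated HN4 held 122 CPM.

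Cal27 with IL-8 replicate 3 and the third HN4 library labelled ACLY stood apart from their replicates, with mitochondrial shares of 1.06% and 2.15% against 3.37% or more and 5.71% or more. Genes read only in HN4 stood lower in the Cal27 library, at 0.216 of the HN4 level against 0.285 and 0.291 (by up to 0.075). This is argued against as the source of its low mitochondrial share, since even if all mitochondrial reads came with HN4 RNA it allows no less than 2.56%. It stays open for other deviations. A length-related bias may take part in the Cal27 library, whose deviations had a rho of -0.393 with transcript length, just beyond the -0.347 to 0.378 of the 34 other libraries. Its GC rho of 0.502 lay within their -0.615 to 0.722. In the HN4 library the rho with GC was 0.191, within that range. The range is wide and includes the other replicates of its group, measured against this library. It therefore cannot decide on such a bias there, and how the RNA was handled was not tested.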
